A study of Mus musculus with 12 samples.

How the data were processed

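Total RNA was taken from bone marrow cells of 12 Shp2 mutant mice on a C57BL/6 background, 12 to 14 weeks old and of both sexes, per the labels. RNA with an integrity number above 7 went into a low-input library kit and was sequenced in pairs of reads on a HiSeq4000. The labels give no sex, cage or sequencing batch for the single mouse. The samples of a group are separate mice per the labels, and the replicate numbers used here only name them.

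The authors' deposited table holds raw read counts per gene, 1 column for each of the 12 mice, with no normalization. The submitters' processing notes name bcl2fastq, STAR 2.7.2a, featureCounts and Subread 1.6.5 with genome build mm10. The annotation release and whether reads were counted by strand are not given in the sources used here. Of the 56350 identifiers 55094 were found in GENCODE M21, all 55094 with the same start and end, and 758 identifiers repeat a gene symbol. Tests ran on identifiers, and symbols and coordinates are those of the table and that annotation. The labels name 5 mg/kg as the dose of both drugs. No reads were aligned here, so a fault of alignment or counting upstream would pass into every value.

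Total counts ran from 15356919 to 27148190 with a median of 19657932, and 18897 to 24194 genes had at least 1 count per library. Pairs of libraries of the same group differed by more than sampling noise (chi-square per degree of freedom 18.0 to 66.3), so no library was counted as a copy of another. Intervals quoted for counts cover counting error only, since PCR copies cannot be told from separate molecules in these counts. The smallest library limits the precision for genes with few counts, and most of the spread lay between mice, with a common biological coefficient of variation of 0.328.

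Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 4 groups (minimum count 10, minimum total 15), which left 17475. Libraries were scaled by TMM (factors 0.929 to 1.07), and CPM values are scaled the same way, except those of Xist and the Y-linked genes, which are over the total counts without the TMM factor. A quasi-likelihood model with 1 mean for each of the 4 groups and robust dispersion was fitted to all 12 libraries, with 8 residual degrees of freedom. The design tested 8 contrasts with edgeR's quasi-likelihood F test: each treatment against vehicle, the combination against each single agent, the interaction (departure from additivity on the log scale), and each drug averaged over the presence of the other. A joint F test asked for any difference among the 4 groups. All tests were two-sided. Adjusted p values follow Benjamini and Hochberg over all tested genes of a contrast, with a threshold of 0.05. Standard errors are those of the log2 change implied by the F statistic.

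The following choices were made before the data were examined: the contrasts, the model, the rule for naming genes, and 34 gene lists, 17 of cell type markers and 17 of pathways. Named genes are, per contrast, the 10 higher and 10 lower with the largest change past the threshold, with no overlap between the libraries compared (a condition not used for the interaction and the averaged contrasts) and a mean of at least 5 CPM in the higher group. Sex-linked marker genes, receptor segments, unnamed gene models, ribosomal pseudogenes and mitochondrial genes were left out of that choice. Where fewer than 5 genes passed, the 5 with the lowest p were named, and 8 genes were named whatever their values (Ptpn11, Lyz2, Dusp6, Spry4, Etv5, Dnmt1, Cdkn1a and Mki67). Within a list up to 4 members with the lowest p could be named, and further list members in the text were chosen after their values were seen. Of the lists, 32 had at least 5 measured members and were tested with camera (limma 3.58.1, log2 CPM with a prior count of 2, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with an estimated correlation served as an alternative, and fry as a test of another question, whether the genes of a list move on balance 1 way, with no comparison to other genes. The lists for S phase and for nucleoside uptake share 2 genes, Rrm1 and Rrm2.

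The edgeR test was tried on counts simulated from the mean CPM and dispersion of each gene and the sizes of the 12 libraries. Changes were set in the combination group, and 16654 genes passed the filter. Of 100 genes changed 2-fold 51% were recovered and of 100 changed 4-fold 78%, 10 of 139 calls fell on unchanged genes, and an unchanged group gave 0 calls. The simulation draws each gene independently and leaves out variation that many genes share within a library, so errors in the real data may be more frequent. Overlaps of effects against the shared vehicle libraries were set against 100 simulations of unchanged groups.

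Alternatives were DESeq2 size factors within edgeR, no low-count filter, a stricter filter, DESeq2 1.42.0, limma-voom, fits of only the groups compared, the summed CPM of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) as a sex covariate, removal of hemoglobin and immunoglobulin genes, and each library left out in turn. After the data were seen, a fit with Lyz2 as a covariate and a fit without the 4 libraries under 200 CPM of Lyz2 were added. The calls were also counted in the 10 splits of each pair of groups and in 100 regroupings of all 12 libraries.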

Results

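Gene expression was measured by RNA sequencing in bone marrow cells of 12 mice with a leukaemia-causing allele of Ptpn11, which encodes the phosphatase Shp2. The allele was activated by LysM-Cre, a Cre recombinase expressed from the Lyz2 locus in myeloid cells, and the mice serve as a model of juvenile myelomonocytic leukaemia (JMML). The series asks by what mechanism the MEK inhibitor PD0325901 (PD-901) acts when it is combined with 5-azacitidine, a cytidine analogue that lowers DNA methylation. MEK is the kinase that activates ERK downstream of Ras and Shp2. The mice formed 4 groups of 3: vehicle, PD-901, 5-azacitidine and the combination. Both drugs were dosed at 5 mg/kg over 4 weeks, PD-901 by mouth in 20 doses and 5-azacitidine into the peritoneum in 5. Each mouse gave 1 library. Total counts were 19006018, 20309847 and 23084859 in the vehicle libraries and 27148190, 16335382 and 26856283 in the PD-901 libraries. They were 15356919, 16313816 and 23278572 in the 5-azacitidine libraries and 18433456, 18933766 and 23839253 in the combination libraries. Of 56350 genes, 17475 had enough counts to be tested.

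Some library properties did not follow the treatment groups, and others moved with them. Lyz2, which encodes lysozyme M and carries the Cre transgene (mm10 chromosome 10, 117277331 to 117282321), was at 172, 147 and 3228 CPM (counts scaled to library size) in the vehicle libraries and at 44.9, 55.9 and 1151 CPM in the combination libraries. Lyz2 stood at 699.6 to 4182 CPM in the 6 libraries of the single agents. Xist, the RNA of the inactive X chromosome, exceeded 100 CPM in 3 of 3 vehicle libraries, 2 of 3 PD-901 libraries, 1 of 3 5-azacitidine libraries and 0 of 3 combination libraries. Mitochondrial transcripts took 1.78, 1.75 and 1.81% of the counts in the combination libraries and 1.01 to 1.73% in the 9 others. The first principal component of the 500 most variable genes held 31.7% of their variance, and vehicle replicates 1 and 2 and combination replicates 1 and 2, the 4 libraries lowest in Lyz2, had its 4 lowest scores. The component after it held 20.0%, with scores of -19.9, -10.8 and -19.1 in the combination libraries, -33.7 in 5-azacitidine replicate 1 and 3.63 to 15.3 in the 8 others. Ptpn11 itself (chromosome 5, 121130533 to 121191397) had mean levels of 130 to 147 CPM in the 4 groups, and edgeR's quasi-likelihood test gave adjusted p = 0.867 for the combination against vehicle.

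**Figure D1:**
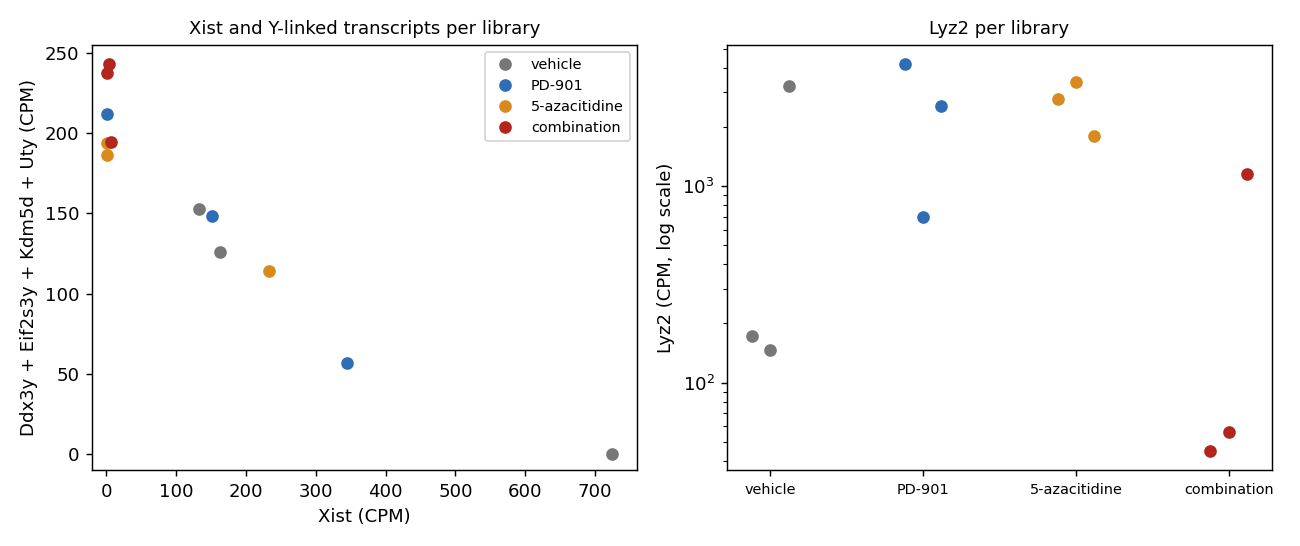
Left, the summed CPM of 4 Y-linked genes against Xist CPM in each of the 12 libraries; right, Lyz2 CPM (log axis) in each library by group. The 3 combination libraries have Xist under 10 CPM, and Lyz2 differs widely between mice of the same group in vehicle and combination.

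PD-901 alone was compared with vehicle to see what the MEK inhibitor did without the second drug. The time from the last dose to the collection of the marrow is not given in the sources used here, so the values do not tell whether MEK was inhibited at that time. Dusp6, the ERK phosphatase transcribed under ERK's control (chromosome 10, 99263231 to 99267489), stood at 205 ± 23.2 CPM with PD-901 and 199.8 ± 23.8 CPM with vehicle (mean ± SD, n = 3; edgeR log2 change 0.04 ± 0.26 SE, adjusted p = 0.999). Hsph1, an HSP110 family chaperone (chromosome 5, 149614287 to 149636376), had the lowest p, at 162 ± 35.8 against 64.6 ± 12.6 CPM (log2 change 1.33 ± 0.19, edgeR adjusted p = 0.0577). It was followed by Cttnbp2nl, with a log2 change of -1.61 (adjusted p = 0.382), and by Sh3pxd2b, Poli and P2rx7, at -1.23, 0.74 and -1.15 (adjusted p = 0.96 each). Other genes named in advance did not pass either, among them the sprouty gene Spry4 (-0.41), the ETS factor Etv5 (-0.53), the cyclin-dependent kinase inhibitor Cdkn1a (-0.32) and the methyltransferase Dnmt1 (0.02).

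With edgeR's quasi-likelihood test 0 genes were higher and 0 lower after PD-901, and 853 had an unadjusted p under 0.05, where chance alone gives 874. DESeq2 called 2 genes higher and 3 lower, and limma-voom 1 higher and 0 lower. Of 32 gene lists fixed in advance, 11 were shifted against the other genes by camera with its preset correlation, and 0 with an estimated correlation. By fry, which tests a list against no change, 0 passed. The S phase and DNA replication list lay upward in 27 of 27 genes (median log2 change 0.26, camera adjusted p = 1.08e-08; adjusted p = 0.685 with an estimated correlation). The erythroid list lay upward in 18 of 18 genes with a median of 0.63, and 6 of them passed when adjusted over the list alone (camera adjusted p = 1.08e-08; adjusted p = 0.685 with an estimated correlation). Hba-a2 and Hbb-bs, adult globin genes, had log2 changes of 2.03 and 1.58 there. The mature B cell list had a median of 1.18 and 5 of 9 genes past the test adjusted over the list alone, led by Fcmr (1.45) and the complement receptor Cr2 (2.17), with camera adjusted p = 4e-05 and adjusted p = 0.685 with an estimated correlation. The immediate early and dissociation stress list had a median of 0.56, 3 of 21 genes past the test adjusted over the list alone and Egr1 at 1.47 (camera adjusted p = 5.37e-05; adjusted p = 0.685 with an estimated correlation). Ribosome biogenesis (median 0.23, camera adjusted p = 0.000377; adjusted p = 0.756 with an estimated correlation) and the B lineage precursor list (0.47, 0.0447; adjusted p = 0.868 with an estimated correlation) also lay upward.

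Downward after PD-901 lay the monocyte list, with 11 of 11 genes negative, a median of -0.51 and 1 gene, Fn1 (-0.90), past the test adjusted over the list alone. Its camera adjusted p was 3.27e-05, with adjusted p = 0.685 with an estimated correlation. The dendritic cell list (median -0.47), the type I interferon response list (-0.27) and the Ras pathway components list (-0.13) had camera adjusted p = 0.0115, 0.0115 and 0.0386. Their values were adjusted p = 0.685, adjusted p = 0.868 and adjusted p = 0.756 with an estimated correlation. The ERK output list had 16 of 19 genes negative, a median of -0.27 and 0 genes past either adjustment (camera adjusted p = 0.0447; adjusted p = 0.756 with an estimated correlation). Hsph1 passed the edgeR test without PD-901 replicate 1, combination replicate 2 or combination replicate 3, and its adjusted p ran from 0.00586 to 0.493 over the 12 fits without 1 library. The combination libraries do not enter the means compared here and bear on the shared estimate of the spread. Without the 4 libraries lowest in Lyz2, a choice made after seeing the data, 11 genes were higher and 6 lower.

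**Figure D2:**
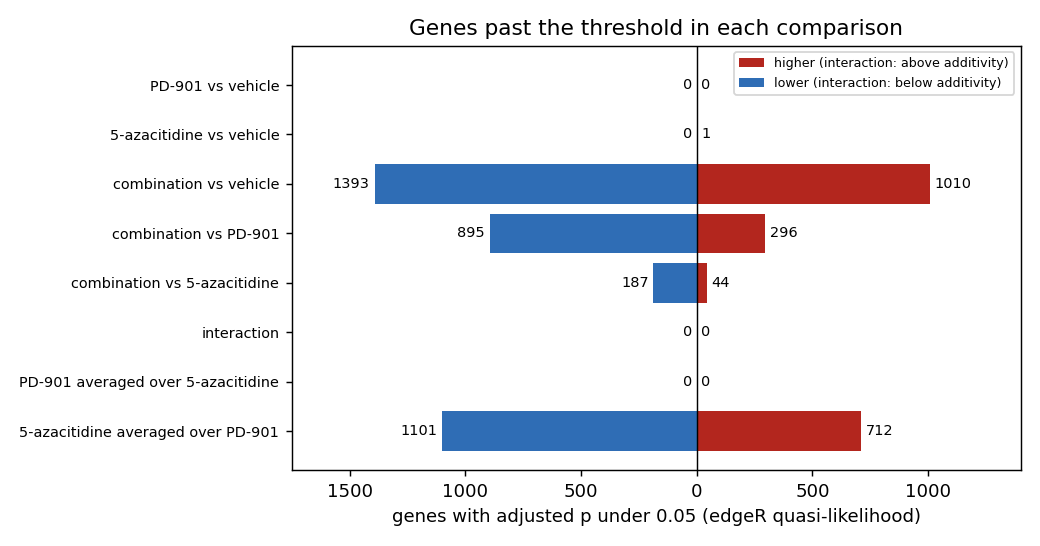
Number of genes with an edgeR adjusted p under 0.05 in each of the 8 contrasts, higher to the right in red and lower to the left in blue. The combination against vehicle has 1010 higher and 1393 lower, and PD-901 alone 0 and 0.

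5-azacitidine alone was compared with vehicle to see what the hypomethylating agent did by itself. Hsph1 was the single gene that rose, to 186 ± 6.01 CPM from 64.6 ± 12.6 CPM (log2 change 1.52 ± 0.19, edgeR adjusted p = 0.0115, n = 3). The chaperone Hsp90aa1 had a log2 change of 1.10 ± 0.17 (adjusted p = 0.0614). Pacsin1, an endocytic adaptor, Ap3s1, a subunit of the AP-3 vesicle coat, and Adam11 had changes of -2.27, 0.92 and -2.82 (adjusted p = 0.0914 each). Dusp6 stood at 171 ± 58.8 CPM (log2 change -0.22 ± 0.26, adjusted p = 0.732) and Dnmt1, the maintenance DNA methyltransferase, had a change of 0.06 (adjusted p = 0.908).

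By camera 15 lists were shifted after 5-azacitidine, 7 upward and 8 downward, none of which passed with an estimated correlation. Proliferation lists lay upward. S phase and DNA replication had a median of 0.37 and 10 of 27 genes past the test adjusted over the list alone (camera adjusted p = 4.44e-09; adjusted p = 0.447 with an estimated correlation), among them the ribonucleotide reductase subunit Rrm2 (0.54) and thymidylate synthase Tyms (0.48). G2 and mitosis had a median of 0.25, with 8 of 23 genes past the test adjusted over the list alone (8.92e-06; adjusted p = 0.447 with an estimated correlation), and ribosome biogenesis 0.36 with 9 of 22 (1.8e-07; adjusted p = 0.447 with an estimated correlation). The neutrophil primary granule list had a median of 0.76 and 7 of 9 genes past the test adjusted over the list alone, with the serine proteases Ctsg at 1.21 and Prtn3 at 1.10 (2.66e-05; adjusted p = 0.447 with an estimated correlation). Erythroid genes had a median of 0.67 with 3 of 18 past the test adjusted over the list alone (3.2e-05; adjusted p = 0.557 with an estimated correlation). Glycolysis and hypoxia (median 0.25, 0.00407; adjusted p = 0.447 with an estimated correlation) and nucleoside uptake and 5-azacitidine metabolism (0.23, 0.022; adjusted p = 0.295 with an estimated correlation) completed the upward set.

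Markers of monocytes and dendritic cells lay downward after 5-azacitidine. Of the dendritic cell list 6 of 12 genes passed adjusted over the list alone, among them Flt3 (-1.11), the plasmacytoid markers Siglech (-2.23) and Ccr9 (-1.80), with a median of -1.13 (camera adjusted p = 2.22e-05; adjusted p = 0.295 with an estimated correlation). Of the monocyte list 7 of 11 passed adjusted over the list alone, led by fibronectin Fn1 (-1.29) and the transcription factor Irf8 (-1.19), with a median of -0.70 (2.66e-05; adjusted p = 0.447 with an estimated correlation). The type I interferon response list had 29 of 29 genes negative and a median of -0.49, with 3 past the test adjusted over the list alone (3.92e-08; adjusted p = 0.447 with an estimated correlation). The stroma, bone and vessel list had a median of -0.74, with 3 of 13 past the test adjusted over the list alone, among them the chemokine Cxcl12 (-1.21) and the pericyte receptor Pdgfrb (-1.30), and camera adjusted p = 0.00255 (adjusted p = 0.295 with an estimated correlation). NF-kB and inflammatory cytokines (median -0.36), megakaryocyte and platelet (-0.47), NK cell (-0.54) and B lineage precursor (-0.34) had camera adjusted p = 0.00454, 0.00653, 0.0213 and 0.0264. The first 3 had adjusted p = 0.557 with an estimated correlation, and the last adjusted p = 0.689.

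In the count of genes edgeR called 1 higher and 0 lower after 5-azacitidine, with 2673 at an unadjusted p under 0.05 against 874 by chance, where DESeq2 called 291 and 322 and limma-voom 2 and 0. Hsph1 lost its call without vehicle replicate 1 or vehicle replicate 2 (edgeR adjusted p up to 0.119) and with Lyz2 as a covariate, and leaving out 5-azacitidine replicate 2 raised the counts to 32 and 74. Without the 4 libraries lowest in Lyz2, added after seeing the data, they were 9 and 17.

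The combination was compared with vehicle to see what both drugs did together. Dusp6 fell 6.32-fold, to 31.6 ± 12.6 CPM from 199.8 ± 23.8 CPM (mean ± SD, n = 3; log2 change -2.66 ± 0.28 SE, edgeR adjusted p = 0.00208), and it kept this call in all 12 fits that left out 1 library (highest adjusted p = 0.00778). In the lists fixed in advance 26 of 27 S phase genes, 12 of 22 of ribosome biogenesis and 16 of 18 erythroid genes rose. Of the markers of mature neutrophils 8 of 12 fell, of monocytes 6 of 11, of dendritic cells 9 of 12 and of B cell precursors 13 of 14, with 21 of 29 interferon response genes and 13 of 20 of the NF-kB list. By camera 19 of 32 lists were shifted against the other genes, and 0 with an estimated correlation, while 13 passed fry, which tests a list against no change. In all, 1010 genes were higher and 1393 lower by edgeR's quasi-likelihood test, 218 and 636 of them by at least 2-fold, and DESeq2 called 1455 and 1953.

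**Figure D3:**
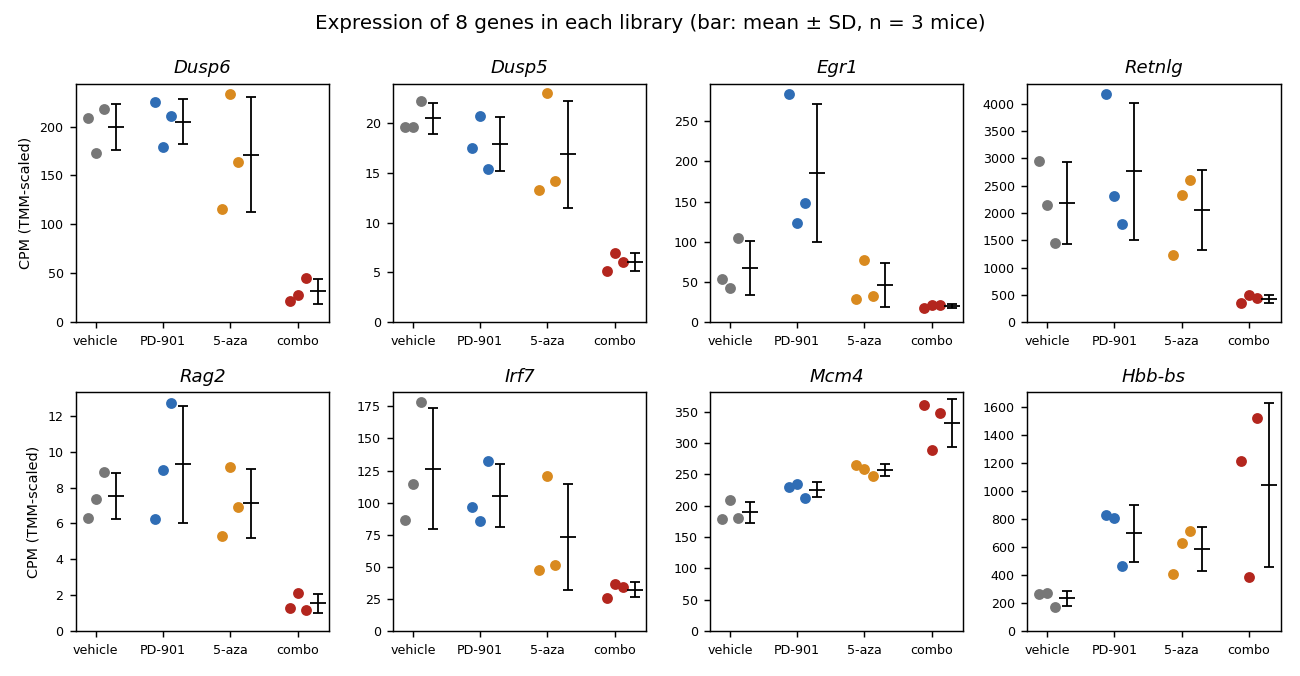
CPM of 8 genes in each library (points) with the mean and SD of each group of 3 mice (bars). In the combination group Dusp6, Dusp5, Egr1, Retnlg, Rag2 and Irf7 have their lowest group means and Mcm4 and Hbb-bs their highest.

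The ERK output list, genes transcribed in response to ERK, had 7 of 19 members lower and 0 higher with the combination, and 8 lower adjusted over the list alone. Besides Dusp6, the nuclear ERK phosphatase Dusp5 fell by 1.75 on the log2 scale and Dusp7 fell by 1.35 (edgeR adjusted p = 0.00251 and 0.00459). Etv5 fell by 1.62, cyclin D1 (Ccnd1) by 2.08 and the receptor tyrosine kinase Epha2 by 2.14. Spry4 did not pass edgeR's test (adjusted p = 0.121). The list's median was -1.47 (camera adjusted p = 7.96e-07; adjusted p = 0.196 with an estimated correlation). Of the immediate early and dissociation stress list 14 of 21 genes fell, and 15 adjusted over the list alone, with Nr4a1 at -2.28, Klf2 at -2.10 and Egr1 at -1.74 (median -1.26, camera adjusted p = 1.4e-06; adjusted p = 0.319 with an estimated correlation). The single member that rose over all genes tested was the chaperone Hsph1 (1.10), with 3 higher adjusted over the list alone. In the Ras pathway components list the adaptor Gab1 rose (1.00) and 5 of 27 genes fell, among them the GM-CSF receptor subunit Csf2ra (-0.98) and the MEK1 gene Map2k1 (-0.58), in the same numbers adjusted over the list alone (median -0.20, camera adjusted p = 0.0131; adjusted p = 0.386 with an estimated correlation).

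Of the S phase and DNA replication list 26 of 27 genes rose, and 27 adjusted over the list alone, with a median of 0.66 (camera adjusted p = 3.38e-17; adjusted p = 0.196 with an estimated correlation). The replicative helicase subunits Mcm4 and Mcm3 rose by 0.81 and 0.74 on the log2 scale, and the licensing factor Cdc6 by 0.97. Mcm4 stood at 333 ± 38.5 CPM against 189 ± 17.0 CPM with vehicle (n = 3). Of the G2 and mitosis list 10 of 23 genes rose, and 20 adjusted over the list alone, led by cyclin B1 (Ccnb1, 0.78) and Aurka (0.65), with a median of 0.48 (7.93e-09; adjusted p = 0.26 with an estimated correlation). Mki67 had a change of 0.58 ± 0.20 (edgeR adjusted p = 0.0715). Of the ribosome biogenesis list 12 of 22 genes rose, and 19 adjusted over the list alone, among them nucleophosmin (Npm1, 0.86) and the pseudouridine synthase Dkc1 (0.81), with a median of 0.61 (4.33e-09; adjusted p = 0.294 with an estimated correlation). In the nucleoside uptake and 5-azacitidine metabolism list 6 of 16 genes rose and 1 fell, in the same numbers adjusted over the list alone (median 0.36, camera adjusted p = 0.0131; adjusted p = 0.196 with an estimated correlation). Rrm1 and Rrm2, which the S phase list also holds, rose by 0.76 and 0.81, the uridine-cytidine kinase Uck2, which phosphorylates 5-azacitidine, rose by 0.65, and the dNTP hydrolase Samhd1 fell by 1.06.

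Of the erythroid list 16 of 18 genes rose, and 17 adjusted over the list alone, with a median of 1.33 (camera adjusted p = 1.4e-08; adjusted p = 0.319 with an estimated correlation). The beta globin gene Hbb-bs rose 4.48-fold to 1044 ± 590 CPM (n = 3), and its libraries ranged widely. Hba-a2 rose by 2.16 on the log2 scale, a call lost without combination replicate 1, the transferrin receptor Tfrc rose by 0.94 and the Rh glycoprotein Rhag rose as well. Erythroferrone (Erfe), an erythroblast hormone that lowers hepcidin, rose 8.64-fold, and Plek2, a pleckstrin of erythroblasts, 16.7-fold.

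Lists of myeloid markers lay in opposite directions by stage. Of the neutrophil primary granule list, which marks promyelocytes, 5 of 9 genes rose, and 6 adjusted over the list alone, among them Ctsg (0.97), Prtn3 (0.90) and myeloperoxidase (Mpo, 0.62), with a median of 0.65 (camera adjusted p = 0.0131; adjusted p = 0.407 with an estimated correlation). Of the neutrophil secondary granule list 3 of 10 fell, and 6 adjusted over the list alone, led by Ly6g (-1.26), with a median of -0.62 (0.00146; adjusted p = 0.386 with an estimated correlation). Of the mature neutrophil list 8 of 12 fell, and 11 adjusted over the list alone, with a median of -1.28 (7.82e-08; adjusted p = 0.26 with an estimated correlation). The stefin Stfa2l1 fell by 2.89 and the resistin-like gene Retnlg by 2.34, to 431 ± 74.2 CPM from 2180 ± 749 CPM (edgeR adjusted p = 0.0029 and 0.00318). Monocyte markers fell in 6 of 11 genes, and in 8 adjusted over the list alone, among them Cx3cr1 (-1.89) and Csf1r (-1.26), with a median of -1.02 (4.44e-06; adjusted p = 0.294 with an estimated correlation). Macrophage markers fell in 4 of 12 genes, with 5 lower and 1 higher adjusted over the list alone, among them the complement genes C1qa (-2.29) and C1qb (-2.54), and a median of -0.84 (0.0179; adjusted p = 0.386 with an estimated correlation).

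Of the dendritic cell list 9 of 12 genes fell, in the same number adjusted over the list alone, with a median of -1.50 (camera adjusted p = 9.61e-07; adjusted p = 0.196 with an estimated correlation). The lectin gene Cd209a (chromosome 8, 3743397 to 3748984) fell 18.5-fold, from 29.5 ± 18.0 to 1.62 ± 0.895 CPM (n = 3), and Siglech and Flt3 fell by 2.38 and 1.20 on the log2 scale. Of the MHC class II presentation list 5 of 10 genes fell, and 7 adjusted over the list alone, among them H2-Aa (-2.18) and the invariant chain Cd74 (-2.03), with a median of -1.31 (0.000936; adjusted p = 0.386 with an estimated correlation). Of the B lineage precursor list 13 of 14 fell, in the same number adjusted over the list alone, with a median of -2.11 (1.02e-09; adjusted p = 0.26 with an estimated correlation). Rag2, a subunit of the V(D)J recombinase (chromosome 2, 101624718 to 101632529), fell to 1.53 ± 0.529 from 7.52 ± 1.30 CPM, and the lineage factor Ebf1 fell by 2.25. Of the basophil, mast cell and eosinophil list 5 of 12 fell, with the basophil proteases Mcpt8 (-1.58) and Prss34 (-1.36), and Siglecf rose (0.84), in the same numbers adjusted over the list alone (median -0.79, 0.00658; adjusted p = 0.386 with an estimated correlation).

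Of the type I interferon response list 21 of 29 genes fell, and 26 adjusted over the list alone, with a median of -1.16 (camera adjusted p = 1.04e-12; adjusted p = 0.26 with an estimated correlation). Ifit3b fell by 3.24, the 2'-5' oligoadenylate synthetase Oas3 by 1.51 and the transcription factor Irf7 by 1.98 on the log2 scale. Of the NF-kB and inflammatory cytokines list 13 of 20 fell, and 15 adjusted over the list alone, with a median of -1.25 (9.31e-10; adjusted p = 0.225 with an estimated correlation). Among them were the inflammasome sensor Nlrp3 (-1.93), the ubiquitin-editing enzyme Tnfaip3 (-1.03) and oncostatin M (Osm, -1.46).

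The other 13 tested lists did not pass camera in this comparison. In the DNA methylation machinery list the chromatin remodeller Hells (0.67) and Uhrf1 (0.50), a partner of Dnmt1, rose and Gadd45a (-0.81) fell, in the same numbers adjusted over the list alone (camera adjusted p = 0.179), and Dnmt1 had a change of 0.43 (edgeR adjusted p = 0.146). Of the p53 targets 3 of 23 rose and 3 fell, with 3 and 4 adjusted over the list alone, and of glycolysis and hypoxia 2 of 20 rose, among them Pdk1 (1.01), and 1 fell, with 3 and 3 adjusted over the list alone (camera adjusted p = 0.635 and 0.388). In the BCL2 family Bmf (-1.30) and Mcl1 (-0.57) fell, and of the NK cell list Prf1 (-1.63) and Ncr1 (-1.30), in 2 and 3 genes adjusted over the list alone (0.254 and 0.106). In the stroma, bone and vessel list Cdh5 (-1.11) and Col1a1 (-0.72) fell, with 3 adjusted over the list alone (0.159). Single genes fell in the mature B cell list (Cd72, -2.75), the plasma cell list (Sdc1, -1.03) and the stem and progenitor list (Gata2, -1.25), with 1 in each adjusted over the list alone (0.233, 0.649 and 0.909). Grb10 rose (1.23) among the imprinted genes, with 0 adjusted over the list alone (0.786). In the T cell, megakaryocyte and platelet, and cholesterol synthesis lists 0 genes passed edgeR's test over all genes or adjusted over the list alone (0.159, 0.254 and 0.807). In the T cell list the lowest unadjusted p belonged to Cd8b1 (1.24, adjusted p = 0.0537). The skeletal muscle list and the methylation-silenced germline genes had 4 measured members each, too few for the list test, and 0 of them passed edgeR's test.

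**Figure D4:**
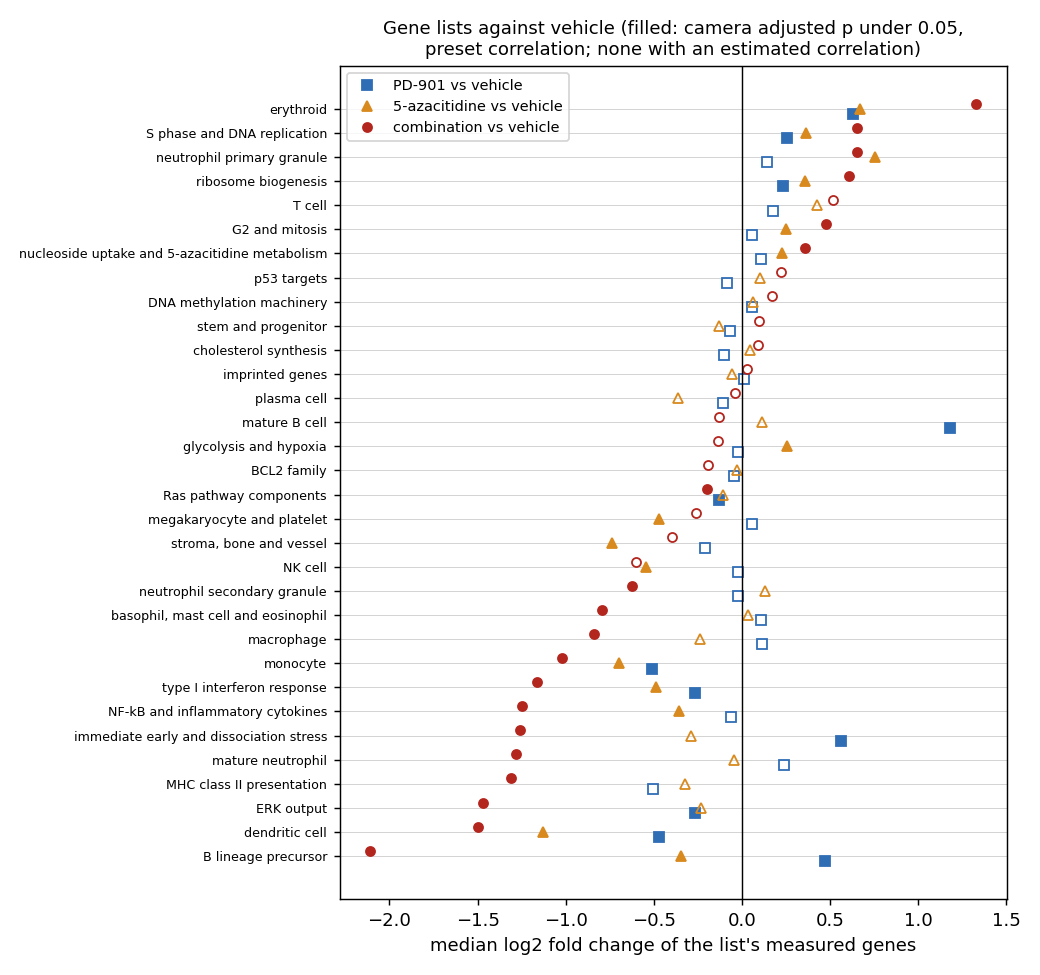
Median log2 fold change of each of 32 gene lists in PD-901, 5-azacitidine and the combination against vehicle; filled symbols passed camera with the preset correlation, and none passed with an estimated correlation. The combination medians run from -2.11 in the B lineage precursor list to 1.33 in the erythroid list.

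Among the genes outside the lists some of the largest rises with the combination were in genes at under 1 CPM in vehicle bone marrow. Podxl, the sialomucin podocalyxin (chromosome 6, 31519488 to 31563981), rose from 0.930 ± 0.402 to 34.1 ± 20.4 CPM (log2 change 5.17 ± 0.71, edgeR adjusted p = 0.0029, n = 3). Apol11b, an apolipoprotein L gene (chromosome 15, 77633946 to 77643286), rose from 0.812 ± 0.667 to 30.7 ± 13.6 CPM (5.27 ± 0.74, adjusted p = 0.0029). Nutm1, which is normally transcribed in testis, had 2 counts in the vehicle libraries together and 383 in the combination libraries, a CPM ratio of 178 (95% exact Poisson interval 49.2 to 1470, counting error only). It also had 53, 6 and 35 counts in the libraries of 5-azacitidine alone and 5, 15 and 0 in those of PD-901 alone. The secreted lectin gene Clec11a rose by 2.88 and the MAP kinase phosphatase Dusp8 by 2.03. Among the largest falls after Cd209a were Igsf9 (-4.12), the monocyte receptor Cd300e (-3.98), the sodium channel subunit Scn4b (-3.81), Havcr1 (-3.76), the C3a receptor C3ar1 (-3.64), Smpdl3b (-3.53), the phospholipid transfer protein Pltp (-3.49) and Slamf9 (-3.05). Genes named by size of change were required to show no overlap between the 3 combination and the 3 vehicle libraries, so that separation is not a result. Lyz2 had a log2 change of -1.50 ± 1.56 (adjusted p = 0.62).

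Of the 22 named genes past the edgeR threshold in this comparison, 17 stayed past it in all 12 fits that left out 1 library; Cd300e, Hba-a2, Pltp, Slamf9 and Smpdl3b did not, each when a combination library was left out. The count of higher genes dropped to 278 without vehicle replicate 1, 574 without vehicle replicate 2, 285 without combination replicate 1 and 381 without combination replicate 3, and the count of lower genes to 728, 925, 518 and 658 in the same order. With the Y-linked level as a covariate 396 were higher and 603 lower, and without the 4 libraries lowest in Lyz2, added after seeing the data, 321 and 349. That last fit has 1 library in vehicle and 1 in the combination, each assumed to vary like the single-agent groups, and 12 of the 22 named genes lost their call in it, among them Podxl (log2 change 3.81, edgeR adjusted p = 0.165), Erfe (2.38, 0.251), Cd209a (-6.39, 0.239) and Etv5 (-1.48, 0.0602). All 12 kept their sign, with a median size of 3.83 on the log2 scale against 3.75 with all libraries. For the genes named by size the rule of no overlap largely fixed that sign in advance, so it is not a result.

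The combination was next compared with PD-901 alone, which shows what 5-azacitidine added in mice that received the MEK inhibitor. Dusp6 was lower (log2 change -2.70 ± 0.28 SE, edgeR adjusted p = 0.00193), Egr1 fell by 3.21 on the log2 scale and the inducible cyclooxygenase Ptgs2 by 4.08. Cdkn1a rose by 0.88. In all, 296 genes were higher and 895 lower, 52 and 463 of them by at least 2-fold. Podxl (4.09), Nutm1 (4.05), Erfe (2.50), Plek2 (2.49), Clec11a (2.38), Apol11b (2.36), Adgrg7 (2.30), the zinc finger gene Mzf1 (2.15) and the palmitoyltransferase Zdhhc2 (1.90) were among the largest rises. Among the genes that the naming rule allows, the largest falls after Ptgs2 were in Scn4b (-3.90), the class I gene H2-Q10 (-3.48), Cd209a (-3.30), the surrogate light chain gene Vpreb3 (-3.26), Egr1, Mid1 (-3.15), Stfa2l1 (-3.15), Krt86 (-3.12) and the lectin receptor Clec4d (-3.05).

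By camera 20 lists were shifted between the combination and PD-901, 6 upward and 14 downward, and 0 with an estimated correlation. Of the B lineage precursor list 12 of 14 genes fell, and 14 adjusted over the list alone (median -2.54, camera adjusted p = 2.54e-13), and of the mature B cell list 4 of 9, and 6 adjusted over the list alone (-1.30, 2.88e-05). They had adjusted p = 0.205 and adjusted p = 0.291 with an estimated correlation. Of the immediate early and dissociation stress list 14 of 21 fell, and 17 adjusted over the list alone, with Zfp36 at -2.41 and Ier5 at -2.39 (median -1.83, 2.04e-12; adjusted p = 0.205 with an estimated correlation). The mature neutrophil list fell in 11 of 12 genes, and in 12 adjusted over the list alone (-1.53, 4.54e-11; adjusted p = 0.205 with an estimated correlation). Interferon genes fell in 15 of 29, and in 24 adjusted over the list alone (-0.90, 1.73e-10; adjusted p = 0.291 with an estimated correlation), and NF-kB and inflammatory cytokines in 11 of 20, and in 15 adjusted over the list alone, with Tnf at -1.90 (-1.12, 2.16e-10; adjusted p = 0.205 with an estimated correlation). In the ERK output list 5 of 19 fell, and 8 adjusted over the list alone (-1.09, 3.83e-05; adjusted p = 0.205 with an estimated correlation). S phase genes rose in 10 of 27, and in 18 adjusted over the list alone (0.41, 1.22e-11; adjusted p = 0.22 with an estimated correlation). G2 and mitosis genes rose in 4 of 23, and in 14 adjusted over the list alone (0.36, 1.41e-08; adjusted p = 0.22 with an estimated correlation). In the erythroid list 0 of 18 genes passed over all genes or adjusted over the list alone, with a median of 0.56 (0.0077; adjusted p = 0.6 with an estimated correlation).

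The 10 other shifted lists against PD-901 were led by cell types. Dendritic cell genes fell in 5 of 12, and in 6 adjusted over the list alone (median -0.91, camera adjusted p = 5.79e-05; adjusted p = 0.205 with an estimated correlation), with the integrin Itgax at -1.64. In the macrophage list 1 of 12 fell, Cd163 (-0.97), and 7 adjusted over the list alone (-0.95, 9.39e-05; adjusted p = 0.225 with an estimated correlation). Basophil, mast cell and eosinophil genes fell in 3 of 12, with 6 lower and 1 higher adjusted over the list alone, among them Ear1 at -1.72 (-0.91, 0.000488; adjusted p = 0.344 with an estimated correlation). Some of these genes also moved with Lyz2. Prg2 stood at 94.48 to 232.2 CPM in the 4 libraries lowest in Lyz2 and at 272.6 to 532.7 CPM in the 8 others. Ear1 was at 14.35 and 18.19 CPM in vehicle replicates 1 and 2, and at 14.71 CPM in combination replicate 3, which is higher in Lyz2. In the neutrophil secondary granule list 2 of 10 fell, and 6 adjusted over the list alone (-0.61, 0.00158; adjusted p = 0.459 with an estimated correlation). In the primary granule list 1 of 9 rose, Ctsg (0.84), with 6 higher and 1 lower adjusted over the list alone (0.52, 0.0254; adjusted p = 0.505 with an estimated correlation). In the monocyte list 1 of 11 fell, and 4 adjusted over the list alone (-0.46, 0.0159; adjusted p = 0.505 with an estimated correlation), and in the NK cell list 1 of 9, Prf1 (-1.60), and 3 adjusted over the list alone (-0.90, 0.0277; adjusted p = 0.505 with an estimated correlation). The MHC class II presentation list had 0 of 10 past either adjustment (-0.85, 0.00182; adjusted p = 0.459 with an estimated correlation). Ribosome biogenesis genes rose in 3 of 22, and in 7 adjusted over the list alone (0.37, 9.11e-06; adjusted p = 0.399 with an estimated correlation). Nucleoside uptake and 5-azacitidine metabolism had 4 of 16 higher and 1 lower, in the same numbers adjusted over the list alone (0.22, 0.0428; adjusted p = 0.205 with an estimated correlation).

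Of the 22 named genes past the threshold against PD-901, 6 stayed past it in all 12 fits without 1 library: Clec11a, Dusp6, Egr1, Podxl, Scn4b and Stfa2l1. The count of higher genes dropped to 35 without PD-901 replicate 1 and the count of lower genes to 326 without combination replicate 1, and with Lyz2 as a covariate, added after seeing the data, 12 genes were higher and 144 lower by edgeR. Without the 4 libraries lowest in Lyz2, which leaves 1 combination library, most of the 22 lost their call. The genes that lost it had a median size of 2.64 against 3.12 on the log2 scale. All of them kept their sign, which the rule of no overlap largely fixed in advance for genes named by size.

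The comparison of the combination with 5-azacitidine alone shows what PD-901 added in mice that received the hypomethylating agent. Dusp6 fell 5.41-fold (log2 change -2.44 ± 0.28 SE, edgeR adjusted p = 0.00614), Dusp5 fell by 1.47, Retnlg by 2.25 and Rag2 by 2.22 on the log2 scale. The stromal genes Pdgfrb (1.87) and Cxcl12 (1.29), at -1.30 and -1.21 after 5-azacitidine alone, were higher, and so was the endothelial receptor gene Adgrl4 (1.33). The 2 falls after 5-azacitidine alone did not pass over all genes. Both comparisons use the same 5-azacitidine libraries, so low values there would give the fall and the rise alike. The stroma, bone and vessel list as a whole did not pass camera against 5-azacitidine. In all, 44 genes were higher and 187 lower, 26 and 95 of them by at least 2-fold. Podxl (4.07), Apol11b (3.38) and Adgrg7 (2.52) were among the largest rises, with the potassium channel gene Kcnk5 (1.86), the co-chaperone Dnaja4 (1.40) and Slc25a42 (1.20) also higher. Besides Dusp6, Retnlg and Rag2, the named genes that fell were Scn4b (-3.31), C3ar1 (-2.72), Clec4d (-2.66), Stfa2l1 (-2.49), Sirpb1a (-2.44), the stefin gene Cstdc4 (-2.34) and the scavenger receptor Stab1 (-2.04).

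By camera 16 lists were shifted between the combination and 5-azacitidine, 4 upward and 12 downward, and 0 with an estimated correlation. Of the mature neutrophil list 5 of 12 genes fell, and 12 adjusted over the list alone (median -1.16, camera adjusted p = 3.26e-11; adjusted p = 0.338 with an estimated correlation). Of the immediate early and dissociation stress list 4 of 21 fell, and 14 adjusted over the list alone, with Klf2 at -1.61 (-1.09, 2.59e-09; adjusted p = 0.338 with an estimated correlation). In the ERK output list 2 of 19 fell, Dusp6 and Dusp5, and 8 adjusted over the list alone (-0.78, 5.4e-08; adjusted p = 0.338 with an estimated correlation). Of the B lineage precursor list 1 of 14 fell, Rag2, and 11 adjusted over the list alone (-1.65, 2.59e-09; adjusted p = 0.338 with an estimated correlation). The S phase list had 1 of 27 higher, the chromatin assembly factor Chaf1b (0.71), and 5 adjusted over the list alone (0.31, 2.61e-09; adjusted p = 0.338 with an estimated correlation). In the erythroid list 0 of 18 passed either adjustment (0.63, 0.000546; adjusted p = 0.509 with an estimated correlation). NF-kB and inflammatory cytokines had 1 of 20 lower, Nfkbia (-0.70), and 13 adjusted over the list alone (-0.98, 2.99e-08; adjusted p = 0.338 with an estimated correlation). Interferon genes had 1 of 29 lower, Oas3 (-1.02), and 6 adjusted over the list alone (-0.60, 3.1e-05; adjusted p = 0.489 with an estimated correlation).

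The 8 further shifted lists against 5-azacitidine had few single genes past the threshold. The neutrophil secondary granule list had 0 of 10 lower over all genes and 8 adjusted over the list alone (median -0.65, camera adjusted p = 3.89e-05; adjusted p = 0.406 with an estimated correlation). Basophil, mast cell and eosinophil genes fell in 2 of 12, Ear1 (-1.90) and Mcpt8 (-1.42), and in 8 adjusted over the list alone (-0.90, 5.47e-05; adjusted p = 0.338 with an estimated correlation). The limit from Lyz2 given for this list against PD-901 applies here too. Glycolysis and hypoxia had 1 of 20 higher, Pdk1 (0.79), with 1 higher and 6 lower adjusted over the list alone (-0.38, 0.000179; adjusted p = 0.338 with an estimated correlation). Over all genes 0 members of the macrophage list (-0.76, 0.00199) and of the MHC class II presentation list (-0.68, 0.00671) passed, with 3 of 12 and 4 of 10 lower adjusted over the list alone, at adjusted p = 0.406 and adjusted p = 0.489 with an estimated correlation. The G2 and mitosis list (0.17, 0.00326) and the ribosome biogenesis list (0.20, 0.0101) had 0 genes past either adjustment, at adjusted p = 0.489 and adjusted p = 0.576 with an estimated correlation. Of the dendritic cell list 1 of 12 fell, Itgax (-1.66), and 2 adjusted over the list alone (-0.12, 0.038; adjusted p = 0.489 with an estimated correlation).

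None of the 20 named genes past the threshold stayed past it in all 12 fits without 1 library. Dusp6 lost its call without 5-azacitidine replicate 3 (edgeR adjusted p = 0.0756). Without 5-azacitidine replicate 2, 5-azacitidine replicate 3 or combination replicate 1 the counts were 0 or 1 in each direction, without combination replicate 3 they were 2 and 9, and in a fit of only these 2 groups 2 and 2. They were 15 and 61 without vehicle replicate 2, 16 and 85 without PD-901 replicate 2, 21 and 128 without PD-901 replicate 3, 77 and 290 without vehicle replicate 3, 114 and 414 without 5-azacitidine replicate 1, 200 and 535 without combination replicate 2, and 0 and 0 with Lyz2 as a covariate. Without the 4 libraries lowest in Lyz2, most of the 20 lost their call. The genes that lost it had a median size of 2.05 against 2.44 on the log2 scale. All of them kept their sign, which the rule of no overlap largely fixed in advance.

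Across the comparisons of the combination with each other group, 19 genes were higher and 161 lower in all 3. These counts cannot exceed the calls against 5-azacitidine, which were 0 and 0 without 5-azacitidine replicate 3. Of the 1393 genes lower against vehicle, the median log2 change was -0.95 with the combination, -0.11 with PD-901 and -0.36 with 5-azacitidine. Of the 1010 higher genes the medians were 0.69, 0.24 and 0.40. These medians share the vehicle libraries on which the genes were picked.

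Whether the drugs departed from additivity on the log scale was tested as an interaction. The genes with the lowest p were Hsph1 (-1.75 ± 0.26), the transcription factor Zhx2 (-2.05 ± 0.31) and Dusp6 (-2.47 ± 0.37), each below additivity with edgeR adjusted p = 0.06, and S100a6 (-1.73) and the gene model Gm11956 (-3.85) with adjusted p = 0.104. With edgeR 0 genes lay above and 0 below additivity past the threshold, with 1871 at an unadjusted p under 0.05 against 874 by chance, where DESeq2 called 75 and 213 and limma-voom 0 and 4. The 4 libraries lowest in Lyz2 all lie in the vehicle and combination groups, so a departure from additivity can also hold that difference. With Lyz2 as a covariate, added after seeing the data, 1149 genes had an unadjusted edgeR p under 0.05. This fit cannot tell the Lyz2 level from a departure from additivity. By camera 10 lists lay below additivity, and 0 with an estimated correlation. They included the immediate early and dissociation stress list (median -1.75, with 15 of 21 below adjusted over the list alone), the mature neutrophil list (-1.35, 12 of 12) and the B lineage precursor list (-2.01, 10 of 14), at camera adjusted p = 1.14e-11, 9.95e-11 and 1.62e-09, each with adjusted p = 0.452 with an estimated correlation. The ERK output list had a median of -0.66 and 2 of 19 genes, Dusp6 and Dusp5, below additivity adjusted over the list alone (0.0019; adjusted p = 0.452 with an estimated correlation). Without 5-azacitidine replicate 1 edgeR called 18 genes above and 132 below additivity, and Dusp6 passed without that library or combination replicate 3 (adjusted p from 0.00508 to 0.293 over the 12 fits).

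Averaged over mice with and without 5-azacitidine, PD-901 gave its lowest p in Cttnbp2nl (-1.37 ± 0.20), Dusp6 (-1.20 ± 0.19) and Apol11b (3.15 ± 0.48), each with edgeR adjusted p = 0.0845, followed by the urokinase gene Plau (-0.73, 0.101) and the Fc receptor gene Fcgr4 (-1.33, 0.135). With edgeR 0 genes passed in either direction, with 2028 at an unadjusted p under 0.05, while DESeq2 called 111 higher and 200 lower and limma-voom 0 and 0. By camera 17 lists were shifted and 0 with an estimated correlation, among them S phase and DNA replication (median 0.28, 22 of 27 adjusted over the list alone, camera adjusted p = 2.41e-15; adjusted p = 0.383 with an estimated correlation), erythroid (0.64, 16 of 18, 1.45e-09; adjusted p = 0.383 with an estimated correlation) and ERK output (-0.68, 6 of 19, 8.55e-09; adjusted p = 0.327 with an estimated correlation). Without combination replicate 2 edgeR called 156 higher and 174 lower.

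Averaged over mice with and without PD-901, 5-azacitidine raised 712 genes and lowered 1101, 47 and 297 of them by at least 2-fold. The 2 comparisons in this average differed in edgeR calls, with 1 gene without PD-901 and 1191 with it. Such counts alone do not show that the effects differ. The interaction, which tests this, called 0 genes by edgeR, and 75 above and 213 below additivity by DESeq2. Of the 1191 genes, 84.8% had the same sign after 5-azacitidine alone. The averaged counts draw on both comparisons, so they do not describe 5-azacitidine alone. The naming rule kept to genes with a mean of at least 5 CPM in the higher group. Among the genes it allows, Podxl (2.59), Erfe (2.26), Apol11b (2.13), Clec11a (1.97), Mzf1 (1.79), Ggt1 (1.51), the prokineticin gene Prok2 (1.44), Zdhhc2 (1.30) and the HSP70 genes Hspa1b (2.06) and Hspa1a (1.38) rose most. Among the same genes Havcr1 (-2.54), Igsf9 (-2.41), Cd209a (-2.37), Ptgs2 (-2.28), Scn4b (-2.20), Siglech (-2.18), Ifit3b (-2.16), Krt86 (-2.07), the lymphoid factor Spib and Cd300c fell most. Dusp6 fell by 1.46 and Cdkn1a rose by 0.55 (edgeR adjusted p = 0.00411 and 0.0302). Without PD-901 the change of Dusp6 was -0.22 (edgeR adjusted p = 0.732), and with it -2.70. For Cdkn1a these changes were 0.23 and 0.88. By camera 21 lists were shifted, 6 upward and 15 downward, and 0 with an estimated correlation. S phase genes rose in 19 of 27, and in 24 adjusted over the list alone (median 0.37, camera adjusted p = 1.09e-13; adjusted p = 0.292 with an estimated correlation), and interferon genes fell in 18 of 29, and in 26 adjusted over the list alone (-0.78, 1.71e-12; adjusted p = 0.292 with an estimated correlation). Of the neutrophil primary granule list 6 of 9 rose, and 7 adjusted over the list alone (0.62, 0.00022; adjusted p = 0.294 with an estimated correlation), and of the dendritic cell list 8 of 12 fell, in the same number adjusted over the list alone (-0.99, 1.87e-06; adjusted p = 0.292 with an estimated correlation). Without combination replicate 1 the counts were 274 and 589, with the Y-linked level as a covariate 199 and 482, and 7 of the 22 named genes lost their call in at least 1 fit without a library: Apol11b, Cdkn1a, Hspa1a, Hspa1b, Krt86, Ptgs2 and Zdhhc2. Leaving out the 4 libraries lowest in Lyz2 cost 10 of the 22 their call, and all 10 kept their sign, with a median size of 1.63 against 1.92 on the log2 scale.

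A test for any difference among the 4 groups called 1217 genes by edgeR. That count was 4 without combination replicate 1, 186 without combination replicate 3 and 136 with the Y-linked level as a covariate.

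The effects against vehicle were set beside each other across the 17475 genes, which are not independent replicates and share the same vehicle libraries. The log2 changes of 5-azacitidine and of the combination had r = 0.559, where unchanged groups against shared controls gave 0.498 in simulation, with a covariance of 0.282 against 0.146 simulated. For PD-901 and the combination r was 0.435 against 0.502 simulated (covariance 0.182 against 0.146), and for PD-901 and 5-azacitidine 0.57 against 0.498 (0.217 against 0.146). The 3 vehicle libraries cannot be divided into separate sets of at least 2, so part of each excess can come from the shared controls. In pairs of effects with no library in common, 5-azacitidine against vehicle and the combination against PD-901 had r = 0.135 (-0.000419 simulated), and PD-901 against vehicle and the combination against 5-azacitidine -0.0944 (-0.000467 simulated). The simulations draw each gene independently and leave out variation that many genes share within a library. They therefore do not show how far any of these r values can stray by chance. Of the 2403 genes called with the combination, 2283 (95.01%) had the same sign after 5-azacitidine and 1896 (78.9%) after PD-901, signs that the shared vehicle libraries also favour. The 1 gene called with 5-azacitidine, Hsph1, was also called with the combination, where 0.0578 were due to chance if the lists were independent. A list of 1 gene, against the same vehicle libraries, tells nothing about overlap.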

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

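The marker comparisons in the last paragraph were chosen after the result was seen, and the tests with a neutrophil or monocyte covariate were written down before they were run. In 10 of the 32 tested gene lists the combination lay below the sum of the single drugs on the log2 scale, a difference between groups that camera called with its preset correlation and lost with an estimated one. The median departure was -1.75 in the immediate early and dissociation stress list (camera adjusted p = 1.14e-11), -1.35 in the mature neutrophil list (9.95e-11), -2.01 in the B lineage precursor list (1.62e-09) and -0.826 in NF-kB and inflammatory cytokines (9.79e-05). It was -1.42 in the mature B cell list (0.000114), -0.915 in the basophil, mast cell and eosinophil list (0.000303), -0.796 in the macrophage list (0.000523) and -0.66 in ERK output (0.0019). With an estimated correlation each of these 8 had adjusted p = 0.452. The neutrophil secondary granule list had -0.628 (camera adjusted p = 0.00403; adjusted p = 0.645 with an estimated correlation) and glycolysis and hypoxia -0.308 (0.0177; adjusted p = 0.616 with an estimated correlation). No single gene passed edgeR's interaction test, and in the immediate early list the PD-901 group lay above vehicle, with Egr1 at 1.47, so its departure also holds that difference. The mature B cell and B lineage precursor lists lay above vehicle after PD-901 as well, so the same limit applies to them. The mature B cell list did not pass camera for the combination against vehicle. In all 10 lists the departure can also hold the Lyz2 difference, since the 4 libraries lowest in Lyz2 all lie in the vehicle and combination groups.

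The fall of Dusp6 and of the ERK output list with the combination has a biological reading, lower ERK signalling per cell, and a reading from the cell mixture, fewer neutrophils or monocytes that carry these transcripts. Whole marrow was measured, and mature neutrophil and monocyte markers fell in the same libraries. With the mature neutrophil markers as a covariate the log2 change of Dusp6 was -2.175 ± 0.47 (edgeR adjusted p = 0.475), and with the monocyte markers -2.501 ± 0.46 (adjusted p = 0.188), from -2.66 ± 0.28 without either. The median of the 7 fallen ERK output genes was -2.09 and -1.30 in these fits, from -1.75, and 0 genes of the whole table stayed past the threshold in either. The covariates lie so much between the groups (82.2% and 64.6% of their variance) that these fits have little power and decide nothing on either cell type.

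If Dusp6 were transcribed in mature neutrophils or in monocytes alone and unchanged in each cell, it could fall no further than their markers. Against vehicle 11 of 12 neutrophil markers and 11 of 11 monocyte markers fell less than Dusp6, the lowest being Stfa2l1 at -2.89 (difference 0.23 ± 0.48) and Cx3cr1 at -1.89 (difference -0.77 ± 0.46). From 5-azacitidine alone to the combination Dusp6 fell by 2.44 while 5 of 11 monocyte markers lay above 0, with a list median of -0.27, and Dusp6 fell further than the lowest of them by more than 2 SE (difference -1.33 ± 0.39). These values argue against fewer monocytes as the whole cause of the fall of Dusp6. In the same step 11 of 12 mature neutrophil markers fell less than Dusp6, with a list median of -1.16. The most fallen of them, Stfa2l1, fell as far as Dusp6 (difference 0.0578 ± 0.47). On this 1 marker fewer late neutrophils could account for the fall. For the other ERK output genes neither cell type is excluded.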

How the results depend on the processing

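No paired analysis was possible because the replicate numbers follow the order of the samples and tie no mouse of one group to a mouse of another. No value past its threshold changed sign. Values of named genes not past it did so 37 times over all alternatives, as in the interaction of Etv5 and of Spry4. Without the 4 libraries lowest in Lyz2 the balance for the combination against 5-azacitidine turned from more lower to more higher. DESeq2 size factors moved no count by more than 1.5 times, and no scaling moved the median change of all genes by 0.1. The calls of the combination against vehicle kept their counts within 1.5 times with all tools and filters. The cause of the moves below was not tested, except that fits of fewer libraries have fewer samples. Genes with few counts are limited by depth, the smallest library having 15356919 counts.

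Counts are given as higher and lower. Without a low-count filter they were 32 and 21 for PD-901 against vehicle, 225 and 347 for 5-azacitidine, 282 and 704 for the combination against 5-azacitidine, 112 and 288 for the interaction, 202 and 337 for PD-901 averaged, with 503 higher for the combination against PD-901 and 2629 for any difference among the 4 groups. With DESeq2 they were 2 and 3, 291 and 322, 288 and 760, 75 and 213, and 111 and 200 in the same order, 763 and 1452 for the combination against PD-901, 1236 and 1705 for 5-azacitidine averaged and 3018 for any difference among the 4 groups. With limma-voom PD-901 had 1 higher, 5-azacitidine 2 higher, the combination against 5-azacitidine 28 higher and the interaction 4 lower. Without hemoglobin and immunoglobulin genes PD-901 had 1 higher. In fits of only the groups compared 5-azacitidine had 4 and 3 and the combination against 5-azacitidine 2 and 2. With the stricter filter the latter had 283 lower.

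With the Y-linked level as a covariate the combination had 396 and 603 against vehicle, 179 higher against PD-901 and 29 higher against 5-azacitidine, 5-azacitidine averaged had 199 and 482, and any difference among the 4 groups 136. Both following alternatives were chosen after seeing the data. With Lyz2 as a covariate 5-azacitidine had 0 higher, the combination 12 and 144 against PD-901 and 0 and 0 against 5-azacitidine, and any difference among the 4 groups 521. Without the 4 libraries lowest in Lyz2, which leaves 1 library in vehicle and 1 in the combination and assumes that each varies like the single-agent groups, the counts were 11 and 6 for PD-901, 9 and 17 for 5-azacitidine, 321 and 349 for the combination against vehicle, 159 and 122 against 5-azacitidine, 2 and 28 for the interaction, 182 and 85 for PD-901 averaged, 282 and 425 for 5-azacitidine averaged, with 454 lower against PD-901 and 551 for any difference among the 4 groups.

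With each library left out in turn the counts ran as follows, higher then lower. PD-901 had 0 to 1 and 0 to 0, and 5-azacitidine 0 to 32 and 0 to 74. The combination had 278 to 1124 and 518 to 1642 against vehicle, 35 to 427 and 326 to 1136 against PD-901, and 0 to 200 and 0 to 535 against 5-azacitidine. The interaction had 0 to 18 and 0 to 132, PD-901 averaged 0 to 156 and 0 to 174, 5-azacitidine averaged 274 to 898 and 589 to 1425, and any difference among the 4 groups 4 to 1674.

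The lists past camera numbered 0 in all 8 contrasts with an estimated correlation. Fry tests a list against no change and not against other genes. The lists past it numbered 0 for PD-901, 4 for 5-azacitidine, 13 for the combination against vehicle, 12 against PD-901, 8 against 5-azacitidine, 0 for the interaction, 2 for PD-901 averaged and 15 for 5-azacitidine averaged. With a library left out PD-901 had 6 to 11 lists past camera.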

Other observations

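The tests with the Y-linked level and with Lyz2 as covariates, the count of Xist by treatment, the correlations within the libraries with high Xist and the choice of heat shock genes below came after the results were seen. The prediction on Xist and its escape genes was written before its test.

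The number of genes called was set against other divisions of the same libraries. For pairs of groups there are 10 splits of 6 libraries into 3 and 3, too few for a share under 0.05. For PD-901 against vehicle 10 of 10 splits gave at least the real count of 0, and the highest other count was 0. For 5-azacitidine against vehicle the number was 2 of 10 (real 1, highest other 2). For the combination it was 1 of 10 against vehicle (2403, highest other 1), 1 of 10 against PD-901 (1191 and 0) and 1 of 10 against 5-azacitidine (231 and 9). Among 100 regroupings of all 12 libraries, 100 gave at least the real count of 0 for the interaction (highest 645) and 100 for PD-901 averaged over 5-azacitidine (real 0, highest 563). Any regrouping reaches a count of 0, so these numbers say nothing about chance, and neither does that for PD-901 against vehicle. For 5-azacitidine averaged over PD-901 only the real grouping, 1 of 100, reached 1813 (highest other 775), and for any difference among the groups 1 of 100 reached 1217 (highest other 240). The regroupings with 645 and 775 divide the libraries exactly by whether 5-azacitidine was given, so these high counts contain the effect of that drug.

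The 2403 calls of the combination against vehicle could come from the sex of the cells or from the Lyz2 level, since both differ between these libraries. With the summed Y-linked level as a covariate the median share of the log2 change kept by these genes was 1.13, with 953 of the 2403 calls (39.7%) kept, 2403 of the same sign, 999 genes called and Dusp6 at -2.60 (edgeR adjusted p = 0.0191). With Lyz2 as a covariate the share was 1.02, with 1732 (72.1%) kept, 2403 of the same sign, 1800 called and Dusp6 at -2.51 (adjusted p = 0.000299). The Y-linked level was 153, 0.148 and 126 CPM in the vehicle libraries and 243, 238 and 195 CPM in the combination libraries. It separates the groups, so this fit cannot tell sex from treatment. Lyz2 was low in replicates 1 and 2 of both groups (log2 change -1.50 ± 1.56 SE), so its covariate could shrink these changes little. Against PD-901 the Lyz2 covariate left 12 genes higher and 144 lower, from 296 and 895. Neither fit decides the cause of the calls, and a part of them may depend on either.

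Xist and Y-linked transcripts were present in the same libraries, which a single mouse of either sex would not give. The libraries form 2 clusters, 6 with 0.515 to 7.59 CPM of Xist and 6 with 132.3 to 723.5 CPM, and 5 of the 6 with high Xist had more than 50 CPM of Y-linked transcripts. Over all 12, Xist and the Y-linked level had Pearson r = -0.943 (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted 2e-05 over 2 relations; -0.907 without the 2 farthest libraries) and Spearman rho = -0.825 (permutation p = 0.0016). Xist and 4 genes that escape X inactivation had r = 0.586 (permutation p = 0.043; 0.364 without vehicle 2 and PD-901 2) and rho = 0.601 (permutation p = 0.043). Within the 6 libraries with high Xist r was -0.961 for the Y-linked level (exact p = 0.0014 over 720 orders; rho -1, exact p = 0.0028; r = -0.896 without the 2 farthest) and 0.914 for the escape genes (exact p = 0.0028; rho 0.943, exact p = 0.017; r = 0.953 without the 2 farthest), each adjusted p 0.0028 over 2 relations. These values are consistent with female and male cells in one library, as after a transplant or a mixing of samples, which the data cannot tell apart. High Xist did not need 5-azacitidine, since 5 of 6 libraries not given the drug had high Xist and 1 of 6 given it. The drug therefore cannot account for the pattern across the libraries. For the 1 library given it these counts decide nothing.

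The heat shock genes below were picked after their values were seen. Hsph1, Hsp90aa1, Hspd1 and Stip1 lay above all vehicle libraries in 9 of 9 treated libraries and Chordc1, Dnaja1 and Hspa1b in 8 of 9. Hspa1a lay above them in 6 of 9 and below them in 1, and the cold-induced Cirbp below them in 8 of 9 and above them in 1. With the combination Hsp90aa1 had a log2 change of 1.03 and Hspd1 1.01 (edgeR adjusted p = 0.00318 and 0.00372), and Hspa1b had 3.09 with 5-azacitidine alone (adjusted p = 0.113). No test was made of whether handling or drug lies behind this.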
